A study of Medicago truncatula with 7 samples.

How the data were processed

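Nuclei were released from roots of Medicago truncatula (a model legume), sorted by flow cytometry after staining and turned into 10x Genomics 3' v3.1 droplet libraries, per the labels' protocols. In such libraries each RNA molecule carries a molecular identifier (UMI) and each droplet a barcode. The labels name 4 libraries from roots inoculated with the arbuscular mycorrhizal fungus Rhizophagus irregularis and 3 from roots that were not inoculated. Harvest days were 21, 28 and 38 days post inoculation (dpi). Nothing in the labels says that libraries came from separate plants or pots, so p-values measure only the spread between these libraries, which can be technical.

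The deposited matrices hold UMI counts per feature and barcode, not normalized, over 94448 features: 52847 plant features (51519 with an MTR locus identifier and 1328 non-coding ones) and 41601 fungal features. The matrices name cellranger 5.0.1, per the file headers, while the submitters' processing notes name Cell Ranger 2.1.1. The genome builds and annotations were not given in the sources used here. The authors also deposited nucleus metadata that give the library, cell type, UMI count and gene count of the nuclei they kept, with 18 cell types over 38096 nuclei in all 7 libraries and 16 clusters over 16890 nuclei in 3 inoculated libraries. Kept nuclei had at least 301 detected features in 5 libraries and at least 201 in the other two, and left-out barcodes had at most 300 and 200. No further filter on nuclei was applied. Cell types were taken from that annotation. Its names for the endodermis disagree. Of nuclei in the cluster named Endodermis, 95.9% are named unknown among the 18 cell types. Of those in the cluster named Unknown, 93.8% are named Endodermis among the 18. Endodermis as a cell type below is the name among the 18, so its identity is uncertain. No doublet caller was run, and no doublet step is described in the sources used here. A reference gene table of the assembly MtrunA17r5.0-ANR matched 0 of the plant identifiers, so it gave no names, and lists to be built from product descriptions were not analysed here. Symbols of 44 listed genes were tied to locus identifiers from published literature before the data were examined. The files name 8 of these 44, and name 46 plant features in all.

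Which matrix belongs to which library needed a choice for inoculated 2 and not inoculated 1, the second 28 dpi set. All 4227 nuclei that the authors' metadata assign to inoculated 2 have their barcode and exact UMI total in the matrix recorded for not inoculated 1, and all 1328 nuclei of not inoculated 1 have theirs in the matrix recorded for inoculated 2. In the other 5 libraries all nuclei match the matrix recorded for them. The metadata were followed throughout. This was decided after the data were examined, and values with the matrices as recorded are given for fungal UMIs, for AM_core and for each list that changed its side of 0.05.

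UMI counts were summed over the kept nuclei of each library, and over each cell type within a library. CPM are UMIs per 1000000 UMIs of the plant features, or of all features for fungal UMIs. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM factors, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. Per cell type it used libraries with at least 20 nuclei of the type and needed at least 3 inoculated and 2 other libraries. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 5 lists, and with an estimated correlation or with fry as alternatives. The lists were AM_core (16 genes tied to arbuscular mycorrhiza), symbiosis signalling (13), strigolactone and carotenoid synthesis (5), phosphate (4), meristem and dividing cells (5) and endodermis (SCR alone, which a list test cannot take). Shares of nuclei, CPM of lists and fungal UMIs were compared with two-sided exact permutation tests of the difference of means over the 35 splits of 7 libraries, where the smallest possible p is 0.0286. For differences between cell types, the mean log2(CPM + 1) of AM_core in all other nuclei was subtracted within each library. Intervals of UMI counts are exact Poisson 95% intervals, and ratios with 1 to 3 UMIs in a group have exact binomial ones. Both cover counting error only. Where a group had 0 UMIs, folds were taken against 3 counts over the group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, DESeq2 1.42.0 and the R package data.table (1.17.8) were also used.

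The rule for named genes took, before the data were examined, called genes by p, each detected AM_core gene and the 4 members with the smallest p of each other list with an adjusted camera p under 0.05. Where fewer than 5 genes passed it took the 5 with the smallest p, leaving out features with no name. Genes named outside it are marked as chosen after their values were seen. The design, the lists and the alternatives were also fixed before the data were examined, except those said to be chosen later. Counts were simulated with the means and library sizes of these 21059 genes, and with the spread that is typical at each mean. The edgeR test recovered 35 of 100 genes changed by 2 on the log2 scale and 99 of 100 changed by 4, with 6 false calls. The changed genes were drawn only from those with an average log2 CPM over 2. The recovery of rarer genes, or of genes with a larger spread of their own, was not measured.

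Alternatives for calls were DESeq2, RLE factors, no filter, limma voom with sample weights, all deposited barcodes, a block for harvest day or for shared title stem, each library left out in turn, the second 28 dpi pair left out, and 28 and 38 dpi alone. Alternatives chosen after the data were examined were the matrices as recorded, no non-coding features, thinning to the shallowest library, the day block without that pair, AM_core without 4 genes or with a library left out, ratios and bounds of genes with few UMIs with an inoculated library left out, fungal UMIs without 2 features and on a log2 scale, lists with the stem block, and lists, shares and cell types without that pair. The title stems in the labels pair 3 inoculated with 3 other libraries. Deviations from the group means correlated within each pair (0.470 at 21 dpi, 0.459 in the second 28 dpi set and 0.472 at 38 dpi). Inoculated 1, which has no partner, gave −0.248 with not inoculated 1 of the same day. It gave 0.380 with not inoculated 3, of another day. The main tests take no block, so values with a block by title stem or harvest day are given where a call was lost with it.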

Results

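Root nuclei were profiled to compare gene expression between inoculated and not inoculated roots by cell type. The 4 inoculated libraries held 7836, 4227, 6797 and 4827 kept nuclei (28, 28, 21 and 38 dpi) with 10981938, 2555863, 9183808 and 5366029 UMIs. The 3 libraries without inoculation held 1328, 6424 and 6657 nuclei (28, 21 and 38 dpi) with 618468, 15162729 and 13958400 UMIs. Inoculated 2 and not inoculated 1 were the shallowest, with medians of 507 and 410 UMIs per nucleus against 950 to 2110 in the others. Ribosomal RNA features took 17.4% and 24.0% of their UMIs and between 2.51% and 9.58% elsewhere, without a difference between groups past the test (9.0 ± 6.13%, SD, n = 4, against 10.8 ± 11.5%, SD, n = 3, exact permutation p = 0.771). The matrices of this pair were assigned by the authors' nucleus metadata, the reverse of how they are recorded.

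Fungal RNA stood higher in each inoculated library than in any library without inoculation. R. irregularis features held 101, 535, 27.4 and 122 CPM in inoculated 1 to 4, and 3.23, 2.44 and 7.52 CPM in not inoculated 1 to 3. The means were 196 ± 229 (SD, n = 4) and 4.40 ± 2.73 (SD, n = 3), a ratio of 44.6, or 19.0 without inoculated 2 and 69.2 without not inoculated 3. The planned exact permutation test did not pass 0.05 (p = 0.0857). On the log2 of the CPM, a scale chosen after the data were examined, the means were 6.86 ± 1.75 (SD, n = 4) and 1.96 ± 0.85 (SD, n = 3), with an exact permutation p of 0.0286, the smallest possible. Fungal features RIR_2491500 and RIR_3144410, singled out after their values were seen, held 75.7% and 84.8% of fungal UMIs in not inoculated 2 and 3 and at most 20.2% in any inoculated library. Without them the ratio was 115, though leaving out features picked for their UMIs in these controls raises the ratio by itself. With the pair's matrices as recorded the direction turned (ratio 0.35, exact permutation p = 0.771), and without both libraries of the pair the ratio was 16.8.

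**Figure D1:**
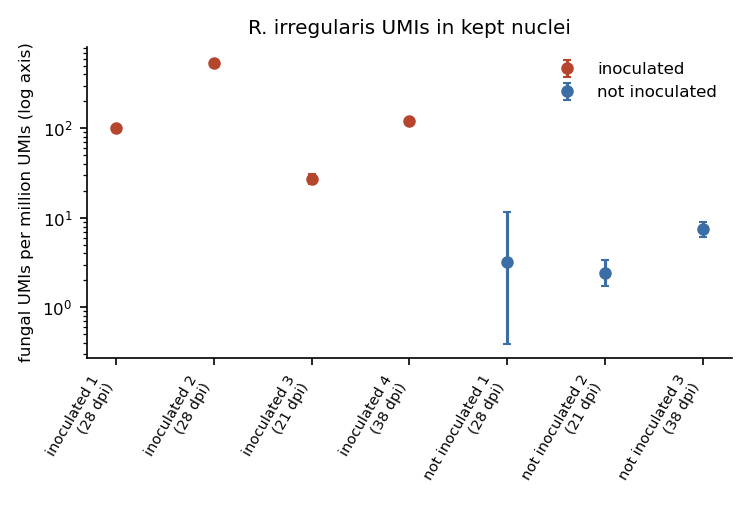
Fungal UMIs relative to all UMIs of kept nuclei (CPM, log axis) in each library, with exact Poisson 95% intervals. The 4 inoculated libraries lie between 27.4 and 535, above the 3 libraries without inoculation at 2.44 to 7.52.

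Of the 16 AM_core genes, 10 had at most 3 UMIs over all libraries without inoculation. PT4 (MTR_1g028600), the phosphate transporter of the membrane around arbuscules, had 61 UMIs over the inoculated libraries and 0 over the others, at least 21.5-fold higher, with UMIs in 4 of 4 inoculated libraries (2.56 ± 1.00 CPM, SD, n = 4). FatM (MTR_1g109110), an acyl-ACP thioesterase of lipid supply to the fungus, had 58 against 3 UMIs (ratio 20.5, counting interval 6.67 to 102). The transcription factor MYB1 (MTR_7g068600) had 80 against 9 UMIs, or 3.92 ± 2.81 CPM (SD, n = 4) against 0.207 ± 0.186 (SD, n = 3). The GRAS transcription factor RAM1 had 34 against 1 UMI (ratio 36.0, interval 6.04 to 1463) and BCP1 39 against 1 (ratio 41.3, interval 6.99 to 1673). With an inoculated library left out, these ratios were 14 to 23.8 for FatM, 27.5 to 44.1 for RAM1 and 20.9 to 56.6 for BCP1, of whose UMIs 27 lay in inoculated 1. The acyltransferase RAM2 had 28 against 0 (at least 9.88-fold higher), RAD1 16 against 0 (at least 5.65-fold), the ammonium transporter AMT2;4 11 against 0 (at least 3.88-fold), the sugar transporter SWEET1b 10 against 0 (at least 3.53-fold) and AMT2;3 3 against 0. Of the SWEET1b UMIs 8 lay in inoculated 4, and without that library the other 2 give no bound above 1. With an inoculated library left out the bounds were at least 19.8 for PT4, 8.29 for RAM2, 4.06 for RAD1 and 2.62 for AMT2;4. AMT2;4 and AMT2;3 had UMIs in 2 of 4 inoculated libraries, and RAD1 and SWEET1b in 3 of 4. PT8 was not detected.

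Other members were present in roots without inoculation. VPY (vapyrin) had 507 against 334 UMIs and a log2 fold change of 0.87 ± 0.35 (SE). The ABC transporter STR had 231 against 141 UMIs (0.81 ± 0.58), and the proton ATPase HA1 90 against 36 (1.66 ± 0.67). With a library left out STR was 0.35 to 1.16 and HA1 1.21 to 2.73, but STR turned to −0.0067 with the matrices as recorded. STR2, the partner of STR, had 63 against 259 UMIs (−1.57 ± 0.80), of which 217 lay in not inoculated 3. EXO70I, an exocyst subunit, had 39 against 64 (−0.37 ± 1.11), of which 62 lay in that library. Without not inoculated 3 these changes were 0.011 for STR2 and 3.30 for EXO70I.

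Of the 8 AM_core genes that passed the filter, PT4, FatM and MYB1 rose with edgeR's quasi-likelihood test adjusted over the list alone (adjusted p = 0.00533, 0.0099 and 0.0099), while 0 passed over all 21059 genes tested. Log2 fold changes were 4.33 ± 1.09 (SE) for FatM and 3.89 ± 0.97 (SE) for MYB1, while the fitted 7.55 ± 1.24 (SE) for PT4 depends on the prior count. FatM's 3 UMIs without inoculation lay in not inoculated 2, so without that library its fit too depends on the prior count. It was 3.44 without not inoculated 3 and 4.50 without inoculated 2, and MYB1 was 3.09 to 4.20 with a library left out. FatM did not pass the filter without inoculated 1, 3 or 4. Adjusted over the list alone, 5 genes passed with DESeq2, 5 with harvest day as a block, 6 with the title stem as a block and 9 without the filter. Without not inoculated 1 it was 5, and 5 without not inoculated 3. Only 2 passed without inoculated 1, 2 without inoculated 3 and 2 without inoculated 4. After thinning 1 passed, the 1 member tested there, and 0 passed with the matrices as recorded. In 7 of the 16 each inoculated library lay above each other library, where chance gives 2.86% of genes.

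As a list AM_core was higher with inoculation (camera adjusted p = 5.83e-06, 6 of 8 members positive), but not with an estimated correlation (adjusted p = 0.0926 with an estimated correlation) or with fry (adjusted p = 0.0764). With the matrices as recorded camera gave an adjusted p of 0.00097, and the log2 fold change of MYB1 turned to −0.48. The summed list stood at 46.7 ± 13.7 CPM (SD, n = 4) against 23.8 ± 13.4 (SD, n = 3), a ratio of 1.96, and 3 of 4 inoculated libraries lay above all others (exact permutation p = 0.114, adjusted 0.343). The ratio was 1.17 with the matrices as recorded. VPY, STR, STR2 and EXO70I were left out after they were seen to be abundant without inoculation, a choice that raises the ratio by itself. The other 12 genes stood at 16.9 ± 6.45 CPM (SD, n = 4) against 1.13 ± 1.16 (SD, n = 3), a ratio of 15 with each inoculated library above all others (exact permutation p = 0.0571), and of 9.75 without the second 28 dpi pair. With a library left out it was 9.97 (without not inoculated 1) to 31.4 (without not inoculated 2).

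**Figure D2:**
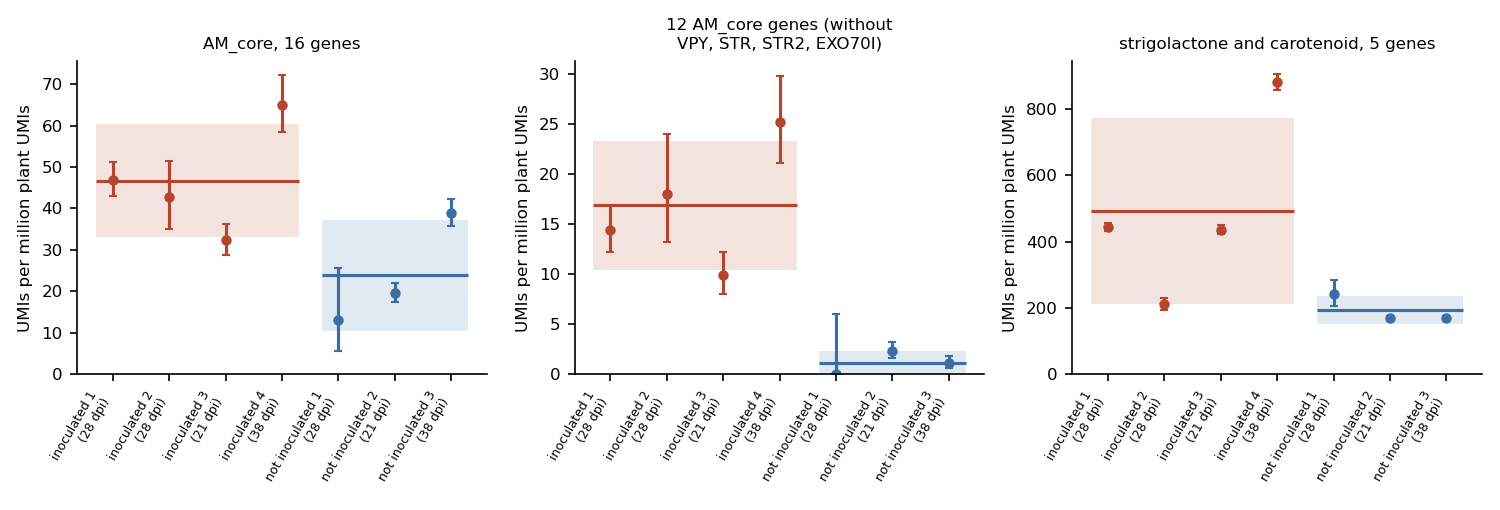
UMIs of 3 gene sets relative to plant UMIs (CPM) in each library, with exact Poisson 95% intervals, and the mean (line) and SD (band) of each group. The 12 AM_core genes lie between 9.91 and 25.2 in inoculated libraries and between 0 and 2.31 in the others, and the full list overlaps between the groups.

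By day, for which no test of AM_core was run and 21 and 38 dpi have 1 library per group, the list in inoculated roots stood at 32.3 CPM at 21 dpi (95% Poisson interval 28.8 to 36.2), 46.9 (42.9 to 51.1) and 42.7 (35 to 51.5) at 28 dpi, and 65.0 (58.4 to 72.2) at 38 dpi. Without inoculation it stood at 19.7 (17.5 to 22.0) at 21 dpi, 12.9 (5.58 to 25.5) at 28 dpi and 38.8 (35.6 to 42.2) at 38 dpi. STR2 and EXO70I made up much of the last, and without these 2 genes the values were 16.8, 12.9 and 18.8.

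Genes of strigolactone and carotenoid synthesis were higher with inoculation as a list (camera adjusted p = 2.75e-07, 5 of 5 members positive), but not with an estimated correlation (adjusted p = 0.0965 with an estimated correlation) or with fry (adjusted p = 0.0835). Strigolactones are root signals to these fungi. The carotenoid cleavage dioxygenase CCD8 stood at 38.5 ± 25.1 CPM (SD, n = 4) against 10.4 ± 2.14 (SD, n = 3), a log2 fold change of 1.79 ± 0.51 (SE). The cytochrome P450 MAX1 stood at 249 ± 133 CPM (SD, n = 4) against 103 ± 11.8 (SD, n = 3), or 1.18 ± 0.41 (SE). CCD7 (1.12 ± 0.64), D27 (1.13 ± 0.70) and DXS2 (1.40 ± 0.86), an enzyme at the entry of the plastid isoprenoid pathway, did not pass. With a library left out these were 0.54 to 1.44, 0.68 to 2.54 and 0.64 to 2.49. CCD8 and MAX1 passed edgeR's test adjusted over the list alone (adjusted p = 0.0344 and 0.0478), 0 passed over all genes, and MAX1 was lost with harvest day as a block (edgeR adjusted p = 0.0598), with RLE factors (0.0515) and without the filter (0.0514). With 28 and 38 dpi alone both were lost (0.199 and 0.211). Both calls were lost when any of 5 libraries was left out, with edgeR adjusted p over the list alone of 0.0574 and 0.082 without inoculated 1, 0.0754 for both without inoculated 3, 0.0717 and 0.123 without inoculated 4, 0.106 and 0.152 without not inoculated 2, and 0.147 for both without not inoculated 3. The list summed to 493 ± 280 CPM (SD, n = 4) against 192 ± 42.1 (SD, n = 3), with an exact permutation p of 0.0857 (adjusted 0.343), and inoculated 2 (211) lay below not inoculated 1 (241).

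Symbiosis signalling genes, some of which act mainly in nodulation, were higher as a list (camera adjusted p = 0.000722), but not with an estimated correlation (adjusted p = 0.209 with an estimated correlation) or with fry (adjusted p = 0.232). Of 13 members 12 had positive fold changes, and 0 passed with edgeR over the list alone or over all genes. The smallest p belonged to the transcription factor ERN1 (1.5 ± 0.57), the receptor kinase NFP (1.03 ± 0.58), IPD3 (0.82 ± 0.48) and NIN (1.18 ± 0.92), each as log2 fold change ± SE. With a library left out they were 1.13 to 1.71, 0.51 to 1.26, 0.44 to 1.39 and 0.66 to 2.40, where NIN passed the filter. The list summed to 952 ± 298 CPM (SD, n = 4) against 765 ± 210 (SD, n = 3), with an exact permutation p of 0.371.

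Of the phosphate genes, SPX3 had 32 against 1 UMI (ratio 33.9, interval 5.66 to 1380), with that UMI in the shallowest library. Per library it stood at 1.18 ± 0.22 CPM (SD, n = 4) against 0.54 ± 0.93 (SD, n = 3), and not inoculated 1 (1.62) lay above each inoculated library (0.98 to 1.49). SPX1 had 85 against 22 (log2 fold change 2.29 ± 0.90, SE, or 1.62 to 2.60 with a library left out), which turned to −0.32 with the matrices as recorded. The transporters PT1 (0.045 ± 0.57) and PT5 (−0.10 ± 1.00) held most UMIs of the list, so its sum went the other way (187 ± 117 CPM, SD, n = 4, against 195 ± 120, SD, n = 3, exact permutation p = 0.971). The list passed camera (adjusted p = 0.0213), with 0 of 4 members past edgeR's test over the list alone or over all genes. The call was lost with an estimated correlation (adjusted p = 0.243 with an estimated correlation), with fry (adjusted p = 0.371), with harvest day as a block (adjusted p = 0.210), and without inoculated 1 (0.186), inoculated 2 (0.199), inoculated 3 (0.0521) or not inoculated 2 (0.260). It was also lost with the matrices as recorded (adjusted p = 0.244). Meristem genes gave a camera adjusted p of 0.428, or 0.0409 without not inoculated 3 and 0.0364 with the matrices as recorded, and SCR, a regulator of endodermis identity, had a log2 fold change of −0.13 ± 0.77 (SE), or −0.54 to 0.66 with a library left out.

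Over all nuclei edgeR called 0 of 21059 genes, with 647 at an unadjusted p under 0.05, of which 314 were higher in inoculated roots. DESeq2 called 44 (40 higher and 4 lower), with PT4 (adjusted p = 0.00303) and MYB1 (adjusted p = 0.0198) among them, and left 110 adjusted p-values undefined. limma voom called 0, with 1693 at an unadjusted p under 0.05. Inoculated libraries lay wholly above the others in 351 genes (1.67%) and wholly below in 379 (1.80%), where chance gives 2.86% each way. The 5 smallest p belonged to loci without a name in the files. Chosen from these after their values were seen, MTR_2g098490 had 6.36 ± 3.27 CPM (SD, n = 4) against 0.022 ± 0.038 (SD, n = 3), MTR_0205s0040 11.6 ± 5.83 against 0.048 ± 0.083, and MTR_8g030733 1.33 ± 0.56 against 11.4 ± 8.79, each with an edgeR adjusted p of 0.748.

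Within cell types, D27, a carotenoid isomerase of strigolactone synthesis, had a log2 fold change of 4.26 ± 0.79 (SE, edgeR adjusted p = 0.696) in Cortex 4. It was 3.57 ± 0.72 (SE, edgeR adjusted p = 0.9997) in the type named endodermis, of uncertain identity, where D27 had the smallest p. These were the 2 entries with a gene name among the 80 of the top 5 by p in each of the 16 types tested. In Cortex 2, which was singled out after its values were seen, PT4 had 40 against 0 UMIs (at least 11.4-fold higher), FatM 40 against 0, MYB1 28 against 0, BCP1 25 against 0 and SPX3 27 against 0. edgeR called 0 genes in the 16 types, with 2832 at an unadjusted p under 0.05. DESeq2 called 24, of which 21 were in Cortex 2. With harvest day as a block edgeR called 3, and without the filter 172.

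AM_core in Cortex 2 held 123 ± 35.1 CPM (SD, n = 4) in inoculated roots against 34.4 ± 13.3 (SD, n = 3). Its mean log2(CPM + 1), minus that of all other nuclei of the same library, was 1.38 ± 0.38 (SD, n = 4) in inoculated and 0.11 ± 0.13 (SD, n = 3) in other libraries. The difference of 1.27, with 4 of 4 inoculated libraries above all others, had an exact permutation p of 0.0571 (0.0857 adjusted over 18 types). In the other 17 types the inoculated mean was the lower, by −0.71 in phloem to −0.05 in LRP 1. LRP 1 had no steady direction, with 0.026 at a pseudocount of 10 CPM and −0.23 to 0.12 with a library left out. All other nuclei include Cortex 2, so a higher Cortex 2 lowers these differences by construction, and none of the 18 types passed (smallest adjusted p 0.0857). The size depends on the pseudocount, with 0.41 for Cortex 2 at a pseudocount of 10 CPM. With the matrices as recorded it was 0.95, with 3 of 4 inoculated libraries above all others, and LRP 1 (0.092) and the endodermis (0.0070) were not lower.

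**Figure D3:**
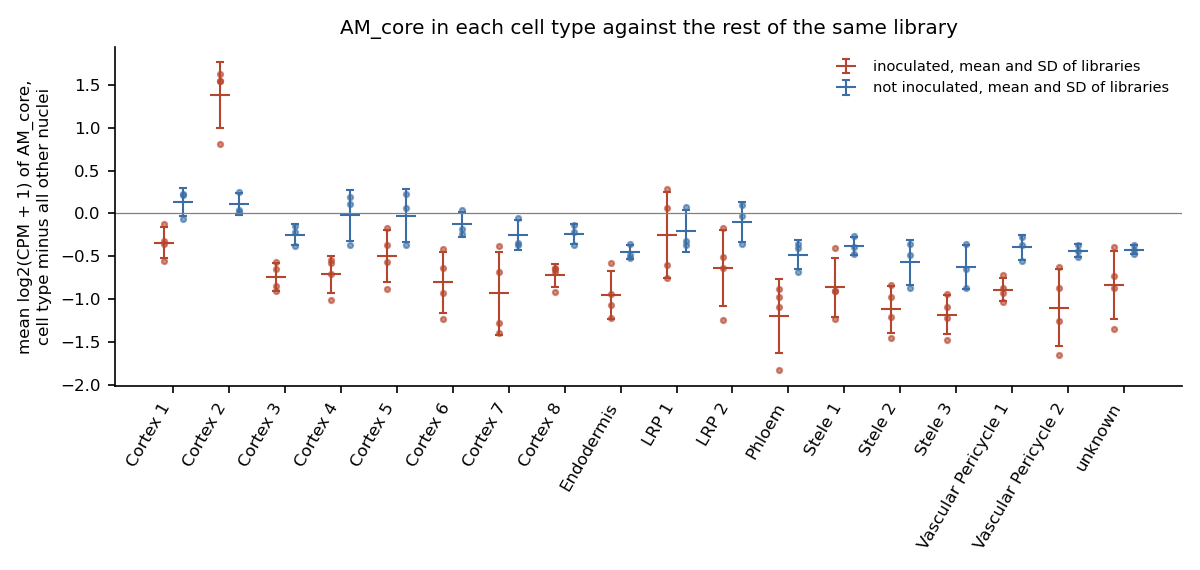
Mean log2(CPM + 1) of AM_core in each of 18 cell types minus that in all other nuclei of the same library, by group, with points for libraries and bars for mean and SD. Cortex 2 of inoculated roots stands at 1.38 against 0.11 without inoculation.

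Shares of nuclei did not differ past the test in any of 18 cell types. Cortex 1 held 16.7 ± 3.29% of nuclei (SD, n = 4) in inoculated and 17.4 ± 8.10% (SD, n = 3) in other libraries, Cortex 2 held 14.2 ± 2.68% and 13.0 ± 4.15%, and the endodermis 3.33 ± 0.73% and 2.72 ± 1.00%. The smallest p was that of Vascular Pericycle 1, at 5.79 ± 0.71% (SD, n = 4) against 4.22 ± 1.21% (SD, n = 3), with an exact permutation p of 0.0857 (0.882 adjusted). Depth differed between libraries, and nuclei of at least 500 UMIs were 27.9% of those kept in not inoculated 1, 51.3% in inoculated 2 and at least 91.4% elsewhere.

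Among inoculated roots at 28 and 38 dpi, the authors' cluster named Colonized Cortex held 174 of 16890 nuclei (1.03%). AM_core reached 1238, 784 and 1790 CPM there in inoculated 1, 2 and 4, against at most 71.3, 179 and 68.2 in the other 15 clusters. The cluster held 173642, 21696 and 60894 plant UMIs in inoculated 1, 2 and 4. Pooled over these libraries, so weighted to inoculated 1, that was 1.36% of plant UMIs. Pooled in the same way, the cluster held 90.9% of the AMT2;4 UMIs (10 of 11), 78.6% of RAM1, 78.3% of SPX3, 66.7% of BCP1, 60.0% of FatM, 56.3% of HA1 and 51.2% of PT4. It held smaller parts of STR2 (49.0%), RAM2 (36.8%), VPY (25.1%), STR (34 of 160 UMIs), EXO70I (19.4%) and MYB1 (17.5%). Strigolactone genes stood at 2183, 830 and 3662 CPM there, against at most 1138, 676 and 2057 elsewhere. Symbiosis signalling genes stood at 1636, 691 and 1429 CPM, against at most 1532, 926 and 1595 elsewhere, so they were highest there in 1 of 3 libraries, while phosphate genes stood at 271, 46.1 and 230 CPM against 818, 1325 and 551 in Cortex 1. Fungal UMIs reached 484, 1611 and 1230 CPM, against at most 356, 877 and 186 elsewhere. However, 1 nucleus of the cluster per library held 20 or more of them. Without such nuclei the values were 139, 701 and 116, against 66.7, 478 and 95.8 in all other clusters pooled. Other clusters were not taken singly in that setting, so these values do not show that Colonized Cortex stayed the highest. Clusters were made from expression, so no test was run. Of the Colonized Cortex nuclei, 71.3% lie in Cortex 2 of the annotation of all 7 libraries.

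**Figure D4:**
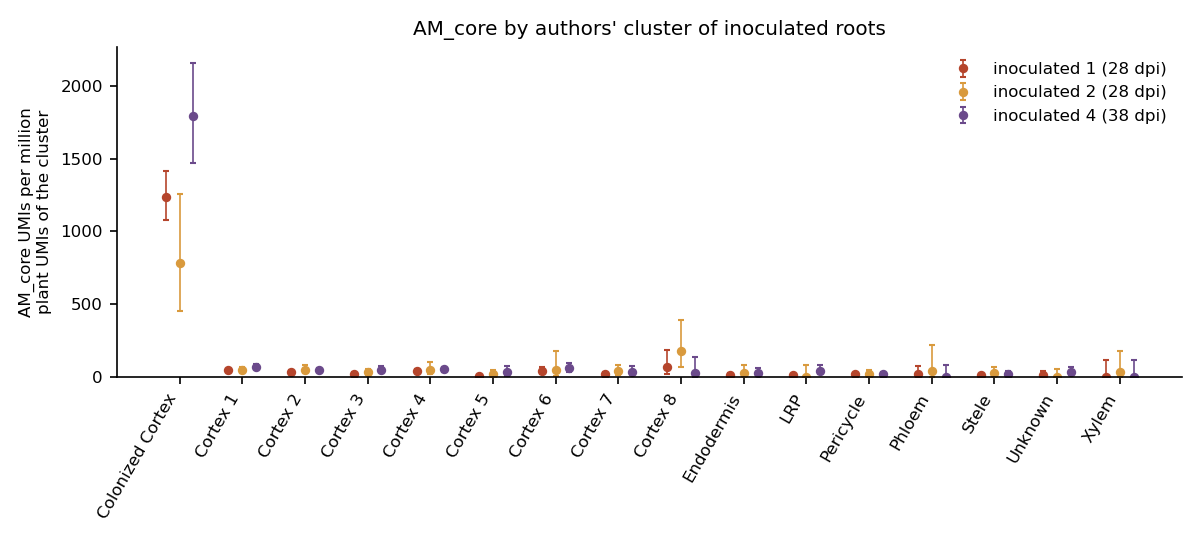
AM_core UMIs relative to plant UMIs (CPM) of each authors' cluster in 3 inoculated libraries, with exact Poisson 95% intervals. Colonized Cortex stands at 784 to 1790, against at most 179 in the other clusters.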

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

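All tests of explanations in this part were chosen after the results were seen. Of 58 values of the inoculated group examined for a library far from the others, 1 stood out, and chance gives about 1 in 20. SWEET1b, a sugar transporter gene, had 1.49 CPM in inoculated 4, with 8 of its 10 UMIs there.

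Barcodes outside the comparisons also held a signal: 13 barcodes that the authors' metadata leave out carried 20 or more fungal UMIs in inoculated libraries, against 0 in libraries without inoculation. In 6 of 7 libraries left-out barcodes as a whole held a larger share of fungal UMIs than kept nuclei. Examples are 8035 against 101 CPM in inoculated 1 and 7220 against 7.52 CPM in not inoculated 3. In not inoculated 3 that was 49 fungal UMIs over 50 left-out barcodes, against 105 fungal UMIs in kept nuclei. Droplets of fungal nuclei would hold mostly fungal UMIs, but 1 of 32417 left-out barcodes in inoculated libraries did, which argues against that source for the pattern as a whole. A candidate explanation is that barcodes were admitted because they held a fungal UMI: in those 6 libraries at least 62.6% of left-out barcodes held one, against at most 19.7% of the kept nuclei with the fewest UMIs (the lowest 10% of each library). What the 13 barcodes are stays open.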

How the results depend on the processing

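Of 114 alternative values of the main results, 104 were counted as unchanged. For a single tested value that meant the same direction and side of the threshold. For calls, lists, shares and cell types it meant the same or a close count of passes, with no check of direction. The Cortex 1 share difference, for example, was −0.66 percentage points in the main setting and 0.82 with nuclei of at least 500 UMIs. Calls over all nuclei were 0 in each alternative but DESeq2 (44). Calls per cell type were 24 with DESeq2, 172 with no filter and 3 with the replicate block of harvest day, and 0 with at least 50 nuclei, without the pair, with the matrices as recorded and with any library left out. The number of lists past camera's adjusted 0.05 was 0 with an estimated correlation, 0 with fry and 3 to 5 with a library left out. AM_core's adjusted p was 0.0926 and 0.0764 in the first 2 of these and 1.89e-07 to 0.00146 with a library left out. Shares and AM_core differences between cell types kept 0 types past 0.05, and the Cortex 2 difference was 1.19 to 1.46 with a library left out. Leaving out a library limits exact permutation p-values to 0.0667 or 0.1, so these say nothing about stability. The fungal ratio was 19.0 to 69.2 with a library left out and turned to 0.35 with the matrices as recorded. It was 177 with all deposited barcodes (exact permutation p = 0.171), which include the left-out barcodes flagged above. The log2 difference of 4.89 passed (exact permutation p = 0.0286). The number of genes past 0.05 adjusted over the list alone was 2 to 5 for AM_core and 0 to 4 for strigolactone genes with a library left out. Apart from the phosphate list, the calls per cell type and the calls adjusted over the list alone, the blocks by pair or day changed no call.

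Of 472 alternative values of named genes and single lists, 402 were counted as unchanged. That meant the same direction and side of 0.05, whatever the size, or a close count of genes past 0.05 over the list alone. With the matrices as recorded, log2 fold changes turned to −0.0067 for STR, −0.48 for MYB1, −0.32 for SPX1 and −0.75 for PT1, by the exchange of 2 libraries between groups. EXO70I turned to 1.46 with voom, 0.38 with the replicate block of harvest day, 0.14 with the block by title stem and 0.047 with the day block without the pair (−1.05 to 3.30 with a library left out). STR2 was −1.96 to 0.011 with a library left out. PT5 turned to 0.68 with voom, 0.22 with the stem block, 0.31 without the pair and 0.30 with the day block without the pair (−1.22 to 1.42 with a library left out). PT1, near 0 in the main setting, turned to −0.00085 with all barcodes, −0.045 with the day block, −0.018 with the stem block, −0.46 without the pair, −0.11 with 28 and 38 dpi alone, −0.20 after thinning and −0.53 with the day block without the pair (−0.39 to 0.70 with a library left out). The meristem list's adjusted p was 0.0409 to 0.935 with a library left out, and its direction turned without inoculated 1 (0.340) and with the stem block (0.855). Other causes were not tested.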

Other observations

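Tests of explanations and counts of splits in this part were chosen after the results were seen, as were the genes singled out. The unnamed loci MTR_2g098490 and MTR_0205s0040 had 119 and 185 UMIs in Cortex 2 of inoculated roots and 0 in Cortex 2 of the others, at least 34.0-fold and 52.9-fold higher, and 69.8% and 63.4% of their UMIs in the authors' clusters lay in Colonized Cortex. In that cluster DXS2 stood at 816 CPM and D27 at 699, against 64.4 and 97.6 in all other clusters. FLOT4, a flotillin, stood at 179 ± 62.2 CPM (SD, n = 4) in inoculated and 86.6 ± 47.2 (SD, n = 3) in other roots (exact permutation p = 0.114).

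The P450 genes CYP716A12, CYP72A67 and CYP72A68 of oleanane saponin synthesis did not differ past the test by inoculation. Their sum was 184, 131, 924 and 478 CPM in inoculated 1 to 4 and 55.0, 632 and 82.2 in not inoculated 1 to 3 (exact permutation p = 0.543). The 2 libraries of 21 dpi lay above the other 5 (exact permutation p = 0.0476, unadjusted, from several genes examined, and the smallest that 2 against 5 libraries can give). The type named endodermis, of uncertain identity, held 52.2% of these UMIs.

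STR2 and EXO70I were highest in not inoculated 3, at 15.5 and 4.44 CPM, against at most 3.91 and 2.98 in any other library. Fungal colonization of those roots would raise the other AM_core genes too, but all 14 of them summed to 18.8 CPM there (95% Poisson interval 16.6 to 21.3), against 30.7 in the lowest inoculated library. Of the 263 UMIs of these 14 genes there, 201 were of VPY and 47 of STR, which were abundant without inoculation. The 12 AM_core genes without VPY, STR, STR2 and EXO70I, chosen after their values were seen, stood at 1.07 CPM there. In inoculated libraries those 12 stood at 9.91 CPM or more. These values argue against colonization as strong as in inoculated roots, as do fungal UMIs (7.52 CPM against at least 27.4). VPY goes the other way, at 14.4 CPM there against 11.4 and 13.1 in inoculated 2 and 3. A larger share of cortex nuclei would not raise levels within a type, yet STR2 stood at 33.5 CPM within Cortex 1 there, against at most 8.70 in any other library, and EXO70I at 15.7 in Cortex 2 against at most 9.11. A difference in how or when this library was grown or made stays open, untested.

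The matrices of the second 28 dpi pair hold each other's nuclei by the authors' metadata. If labels were exchanged in the metadata, nuclei labelled inoculated should be at control level in fungal UMIs, but they held 535 CPM, which argues against it. Matrices recorded for the wrong sample in the deposit are a candidate explanation: kept nuclei in the matrix recorded for the inoculated sample held 3.23 CPM, under the 7.52 of the highest other library without inoculation. The assignment rests on barcodes and UMI totals, and these fungal values were also seen before the test was written.

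Other splits of the 7 libraries into 4 and 3 were counted for each model over many genes. For AM_core, 1 of 35 splits, the real one, gave a camera p as small (2.33e-06, smallest other 7.85e-06). That is the smallest share this count can give, reached by a small margin and only over splits that ignore the title pairs. The share was under 0.05 for this list taken alone. It was not adjusted for the other lists counted in the same way, so chance is not excluded. Among the 8 splits that part all 3 pairs the count was 1 of 8, too few for a share under 0.05, so chance within pairs stays open. The share under 0.05 also rests on the matrices as assigned. As recorded, 6 of 35 splits gave a p as small (0.000582), and chance is not excluded even for this list alone. Nor can chance be excluded for the strigolactone list (4 of 35 splits, real p 5.50e-08, smallest other 6.17e-10), for symbiosis signalling (4 of 35, 0.000433 and 3.55e-06), for phosphate (10 of 35, 0.0171 and 4.03e-05) or for the meristem list (25 of 35, 0.428 and 0.00581). Among the 8 splits that part the pairs, 3, 2, 1 and 6 gave a p as small for these 4 lists. With 0 called genes the real split is matched by all 35, over all nuclei (highest other 134) and per cell type (highest other 3939). The highest in both set the 21 dpi pair and the second 28 dpi pair against inoculated 1 and the 38 dpi pair, and its cause was not tested.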
